A study of Homo sapiens with 8 samples.

How the data were processed

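RNA of 4 Hodgkin lymphoma cell lines was measured on 8 Agilent 2-colour whole human genome arrays. Per the labels, the lines were grown without treatment in medium with 10% serum, total RNA was extracted, and 250 ng per sample was labelled with Cy3 or Cy5. Groups were taken from the labels: 2 arrays each of L591 against L428, L1236 and KMH2, and 2 of L591 against itself. In the groups with an uninfected line, replicate 1 held that line in Cy3 and L591 in Cy5, and replicate 2 the reverse. The first slide held a self-hybridisation and both L428 arrays, another a self-hybridisation and both L1236 arrays, and the last both KMH2 arrays.

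The intensity values of each spot and of its local background were extracted from the scans with Agilent Feature Extraction, version 10.1.1.1 per the file headers and 10.5.1.1 per the submitters' processing notes. The same deposited files held background-subtracted, dye-normalized intensities and the log10 ratio of Cy5 over Cy3, and other columns with flags for signal well above background, saturation and outliers, per the file headers. The deposited series table held the log10 ratio of each array, with a largest difference of 0 from the scanner files where both had a value, 2499 to 5107 empty cells per array, and column medians of -0.0072 to 0.0148. Its scale, centring and direction were thus settled. The files held no mean signals, so median spot signals took their place in the planned processing.

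Each array had 45015 spots, 1639 of them controls. Background was corrected with normexp (offset 50) on the spot and local background medians, followed by loess within each array with control spots at weight 0 (limma 3.58.1 in R 4.3.3, with Python 3.11.15 for the plots). On L428 replicate 1 a patch of spots had a local background of up to 10795 in Cy3 and 9858 in Cy5, and the fitted background mean was -262 and -305, against 20.9 and 1.52 without spots that carried a non-uniform background mark. On every array such spots therefore took the array's median background during the fit and were then left out. This choice was made after the values were seen, and the count with them kept stands beside the main result. Outlier spots were left out and saturated spots kept. Spots of a probe were averaged. A probe was tested if it was well above background in every channel of at least 1 of the lines. Probes of the Y chromosome and XIST (63) and 178 probes with a missing value were left out. All sample columns of the files were assigned to a sample.

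The files carry no gene names. RefSeq accessions of the probes were matched without versions to a table of the GRCh38.p14 assembly, used for names only. Of 41000 distinct probes, 23680 matched 16422 genes, and the others remained unnamed. A gene was represented by its probe of highest mean intensity. Of 5065 genes with several probes, 188 had a call, 0 were called in opposite directions and 122 were called by some probes only. Probes of near-identical genes, such as HLA-DRB, MAGEA and CT45 family members, can bind more than 1 transcript, so their values are not specific to a single gene.

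For L591 against the uninfected lines, each dye-swap pair was turned to L591 over the other line and averaged, since nothing shows that the arrays of a pair held separate RNA extracts. The 3 line values were tested against 0 with limma (lmFit and eBayes, 3.21 residual degrees of freedom with the prior). This leaves out the spread of L591 between cultures, and with 1 infected line the infection and the line coincide. The single-line comparisons and the F-test between lines used all 8 arrays with a dye term (9.55 degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with camera (preset correlation 0.01) on gene values, again with an estimated correlation, and with fry. With the preset, camera takes its degrees of freedom from the genes, so its p rests on their number rather than on that of lines. With an estimated correlation it takes them from the 3 lines, which leaves little power. A call lost there is thus no measure of correlation within the list. Fry, which does not compare a list with other genes, gave an adjusted p of 0.0054 for B-cell identity and for NK markers, 0.0109 for epithelial, 0.0375 for chemokine, and 0.0483 for EBNA2 and for checkpoint genes, and none of the other lists passed.

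The tests, the lists and the rule for named genes were fixed before the data were examined, with exceptions. Added afterwards were the counts beyond 1 in all 3 or in opposite directions, those with another shared line, the tests on the split of the lines, on EBV and on T-cell RNA, and the replicate block for the lists. The removal of uneven spots from the background fit was also decided afterwards, and the fit made first kept them. Named were the 10 genes of largest positive and 10 of largest negative ratio past the threshold with the same sign on all 6 arrays, the 5 of each direction per single line not yet named, the 6 of largest range between lines, up to 4 members of each list with the smallest p, and a fixed set of B-cell, Hodgkin, NF-kB and JAK-STAT genes. Some of the genes this rule takes are not reported here. In the list accounts, further members past the threshold were named too, chosen after their values were seen, as were CAV1, IGLL1 and the second probes of named genes. The 23 lists were NF-kB and LMP1 targets, EBNA2 and EBV growth programme, interferon-stimulated, MHC class I, MHC class II, B-cell identity, plasma-cell, immunoglobulin, Hodgkin markers, JAK-STAT, cytokines, chemokines, checkpoint, apoptosis, cell cycle, DNA repair and p53, cancer-testis, ribosomal protein, T-cell, NK, myeloid, fibroblast and endothelial, and epithelial genes. The immunoglobulin list fell under the minimum size of 5 measured genes, which left 22.

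Where a gene was not well above background in a line, the fold is a lower bound. The mean of the brighter line, over all its channels or on the arrays it shared with the dim line, whichever gave the smaller fold, was set against the dim line's mean of, per array, the higher of the lowest signal well above background and the dim probe's own signal (log2 values per channel after loess and Aquantile). Where only some channels of a line were well above background, the ratio is given as measured, with its size limited by background. In both cases the SE and p over the lines rest partly on background signals as well. Besides those counted in the report, they included BTLA in L1236 and KMH2, POU2AF1 in L428 and KMH2, IL1A and SPI1 in L428, MAGEA1 in L1236, and MS4A1 and PDCD1LG2 in KMH2 (1 of 2 channels each), and in L591 IL13 (5 of 10), GATA3 and PDCD1LG2 (7), MS4A1 (8), and FCER2 and SPI1 (9).

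Replicate numbers mark the dye orientation, and deviations of same-numbered arrays from their group means correlated at 0.695, 0.725 and 0.742, so the numbers paired the arrays through the dye. A dye effect was called at 15376 probes. Spike-in log ratios had slopes of 0.814 to 0.872 against their nominal values. The precision rests on 3 lines and 2 arrays per line, and replicates may be technical.

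The fits were tested on simulated data with the real probes, 50 changed per fold size. For L591 against the uninfected lines, each probe's observed spread between lines was taken as its true spread. At 2-, 4-, 16- and 64-fold, 0, 26, 34 and 42 of 50 were recovered, with 3 false calls among 35579 probes. With 1 spread for every probe, 48, 50, 50 and 50 were recovered, with 7 false calls. Lines were drawn independently, without the L591 RNA that the real ratios share, so these false calls do not measure that design's error rate. For L591 against L428, 32, 46, 49 and 50 of 50 were recovered at 1.25-, 1.5-, 2- and 4-fold (10 false calls), and for differences between lines 18, 40, 47 and 50 (4 false calls). The list test called 1 of 1 shifted list and 0 others among 15315 genes. Genes were drawn independently there, while the correlation estimated within real lists reached 0.623 (cancer-testis). The simulation therefore cannot show how often correlated lists are falsely called.

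Alternatives were no background correction, Agilent's processed signals, the series table, median centring, scale normalization between arrays, no filter and a strict filter on dim probes, an intensity trend with a robust prior, fits without the dye term, with slide as a random block or, on 6 arrays, with the replicate number as a fixed block and the line as a random block, means over all probes of a gene, and leaving out each array or line.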

Results

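Messenger RNA levels were compared among 4 cell lines derived from Hodgkin lymphoma, a tumour of B-cell origin. L591 carried Epstein-Barr virus (EBV), a herpesvirus that infects B cells, and L428, L1236 and KMH2 did not. All lines were untreated. Each of the 8 arrays measured a pair of RNA samples in the dyes Cy3 and Cy5. L591 was hybridised against each uninfected line on 2 arrays with the dyes swapped, and against itself on 2 further arrays. The median spot signal was 177 to 234 in Cy3 and 314 to 504 in Cy5, over local backgrounds of 25 to 28.5 and 35 to 36. Between 73.3% and 84.5% of spots were well above background in Cy3 and between 86.6% and 92.7% in Cy5. The small number of arrays and of lines limited the precision. After filtering, 35579 probes were tested, and those with a gene name covered 15315 genes.

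The first comparison set the infected line against the uninfected lines, the question posed by the series design, with each uninfected line as 1 replicate (n = 3). G0S2, an inhibitor of fat breakdown, was 196-fold higher in L591 (log2 ratio 7.62 ± 0.104 SE, adjusted p = 0.0155, limma), with ratios of 7.44, 7.74 and 7.68 against L428, L1236 and KMH2. CD2, an adhesion molecule best known from T cells and NK cells, was 101-fold higher (6.66 ± 0.208, adjusted p = 0.0155). PRNP, which encodes the prion protein, fell (-5.98 ± 0.242, adjusted p = 0.0190), though it was well above background in only 3 of 10 L591 channels, so that the size of the ratio rests on signals near background. In all, 732 probes passed the threshold, 623 of them higher and 109 lower in L591, and all 732 had the same sign on 6 of 6 arrays. They covered 423 named genes, 365 higher and 58 lower, while 180 of the probes had no gene name. The shared sign is not further evidence, since the 2 arrays of each swap correlated at 0.965 to 0.973. Most called probes were also higher in the single line when another line was set against the rest. These were 37 of 39 for L428, 467 of 602 for L1236 and 1483 of 2266 for KMH2, so the skew was not particular to L591.

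The other genes with the largest rises were the mesodermal transcription factor TCF15 (6.04 ± 0.0944), SCRN1 (5.92 ± 0.140), the transcription factor CEBPD (5.87 ± 0.185) and the matrix protease MMP7 (5.48 ± 0.468). They were followed by PCOLCE2, an enhancer of procollagen processing (5.26 ± 0.0773), the prohormone-processing enzyme CPE (5.19 ± 0.0979), the neutrophil-attracting chemokine CXCL1 (5.07 ± 0.102) and PREX1, an activator of the GTPase Rac (5.06 ± 0.426). CXCL1 was not well above background in KMH2, where L591 was at least 30.5-fold higher (adjusted p = 7.19e-11). The other largest falls were in GTSF1, a factor of the piRNA pathway (-4.79 ± 0.212), DRC9, a subunit of the ciliary dynein regulatory complex (-4.65 ± 0.0808), the tumour antigen PRAME (-4.61 ± 0.398), the palmitoyltransferase ZDHHC11 (-4.56 ± 0.241) and FOXP1, a transcription factor of B-cell development (-4.06 ± 0.197). The tumour antigen MAGEB2 (-3.97 ± 0.187), the mRNA-binding protein IGF2BP1 (-3.92 ± 0.328), the nuclear receptor NR2F1 (-3.25 ± 0.105) and TMEM71 (-3.21 ± 0.162) completed the set. In L591, GTSF1 was well above background in 6 of 10 channels, IGF2BP1 in 7, TMEM71 in 8, and FOXP1 and NR2F1 in 9, and CPE was so in 1 of 2 channels of each uninfected line, as was CXCL1 in L428 and L1236, which limits these ratios as well. For CPE and CXCL1 the SE and p also rest largely on signals near background in the uninfected lines. Adjusted p (limma) lay between 0.0155 and 0.0492 for all 20 genes. A second probe did not pass for DRC9 (0.12, adjusted p = 0.575) or for PRAME (-2.88, adjusted p = 0.0710). Second probes passed at smaller ratios for TCF15 (2.60), ZDHHC11 (-3.74), FOXP1 (-3.29) and IGF2BP1 (-1.77), so the sizes depend on the probe.

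**Figure D1:**
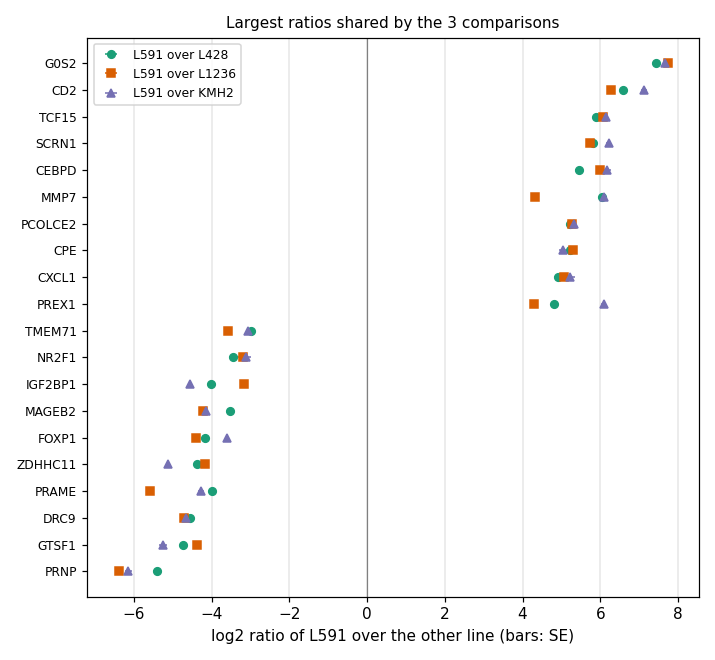
Log2 ratio of L591 over each uninfected line (horizontal axis) for the 10 largest rises and 10 largest falls past the threshold (vertical axis), with a symbol per line and bars for the standard error. The 3 ratios of G0S2 lay between 7.44 and 7.74, and those of PRNP between -6.39 and -5.41.

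The count rested on having all 3 uninfected lines and on how spots with an uneven local background were treated: limma called 0 probes without L428, without L1236 or without KMH2 (4857, 5549 and 5873 probes at an unadjusted p under 0.05), and 0 probes (6370) when such spots stayed in the background model, and their removal was chosen after the values were seen. Without background correction 734 probes passed, with Agilent's processed signals 605 and with the deposited log ratios 630, whereas a fit of the 6 arrays with the replicate number as a fixed block and the line as a random block (correlation 0.955) gave 3875, 64.2% of them higher against 85.1% with 3 lines as replicates. The 6-array fit counts both arrays of a swap as observations, though they may hold the same RNA extract.

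Genes of the EBV growth programme, which the viral protein EBNA2 drives in infected B cells, were higher as a group: 2 of 23 measured members rose, 0 fell and 21 did not pass, with a median log2 ratio of 1.85. The kinase PIM2 (4.14 ± 0.218, adjusted p = 0.0237) and the transcription factor BATF (1.66 ± 0.115, adjusted p = 0.0364) rose. TNFRSF8, the Hodgkin marker CD30 (3.26 ± 0.342, adjusted p = 0.0657), and EBF1, a transcription factor of early B cells (2.30 ± 0.291, adjusted p = 0.0840), did not pass. The list members FCER2 (-0.36) and MYC (0.80) did not pass either, and CR2 had no probe with a matched name. EBF1 was not well above background in L1236, where L591 was at least 7.49-fold higher (adjusted p = 4.38e-11). Adjusted over the list alone, 12 members were higher and 0 lower. The group's shift passed camera (adjusted p = 9.72e-07), though not with an estimated correlation (adjusted p = 0.533 with an estimated correlation). Among targets of NF-kB and of the viral protein LMP1, 1 of 30 members rose, 0 fell and 29 did not pass (median 0.90, with -0.10 against L1236; camera adjusted p = 0.123). The member that rose was EBI3, a cytokine subunit first found in EBV-infected B cells (3.33 ± 0.215, adjusted p = 0.0329). The chemokines CCL22 (2.93 ± 0.366, adjusted p = 0.0827) and CCL5 (-2.23 ± 0.251, adjusted p = 0.0714) and the membrane protein CD82 (2.25 ± 0.283, adjusted p = 0.0831) did not pass. In that list 5 were higher and 2 lower adjusted over the list alone, and without L1236 the group passed (adjusted p = 0.0280).

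B-cell identity genes were higher in L591: 7 of 28 members rose, 0 fell and 21 did not pass, with a median of 1.08. Among those that rose were the B-cell receptor subunits CD79A (2.78 ± 0.108, adjusted p = 0.0181) and CD79B (2.39 ± 0.113, adjusted p = 0.0217) and the adaptor BANK1 (5.05, adjusted p = 0.0206), as well as CD22 (2.27), POU2F2 (2.46) and the kinase SYK (1.90). MS4A1, which encodes CD20, had a ratio of -0.01 (adjusted p = 0.964), and PAX5, the regulator of B-cell commitment, one of 0.92 (adjusted p = 0.0702). Adjusted over the list alone, 15 were higher and 1 lower, and the shift passed camera (adjusted p = 2.79e-07; adjusted p = 0.527 with an estimated correlation). The correlation estimated for this list was -0.019, below the preset 0.01, so correlated members did not make that loss. Of 15 plasma-cell genes, 3 rose, 0 fell and 12 did not pass (median 0.60). TNFRSF17, the survival receptor of plasma cells (4.06 ± 0.0889, adjusted p = 0.0155), JCHAIN, which joins antibody subunits (3.12 ± 0.0961, adjusted p = 0.0155), and DERL3, a protein of the secretory pathway (1.20 ± 0.0993, adjusted p = 0.0475), rose, while PRDM1, the plasma-cell regulator, had a ratio of 2.85 (adjusted p = 0.0573). A second DERL3 probe did not pass (0.50, limma adjusted p = 0.108). Of the plasma-cell genes 5 were higher and 1, CAV1, lower adjusted over the list alone. The plasma-cell shift had an adjusted p of 0.0154 (adjusted p = 0.533 with an estimated correlation), which was 0.111 without KMH2. Of the immunoglobulin list only JCHAIN and IGLL1 (2.06, adjusted p = 0.235) were measured, too few for a test.

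Antigen presentation genes were also higher as groups. For MHC class II, which presents peptides to helper T cells, 1 of 20 members rose, 0 fell and 19 did not pass, with medians of 1.32, 2.48 and 0.80 against L428, L1236 and KMH2. HLA-DOB, a regulator of peptide loading, rose (1.93 ± 0.141, adjusted p = 0.0397), and the invariant chain CD74 (2.34, adjusted p = 0.161), the lysosomal enzyme IFI30 (2.31, adjusted p = 0.0709) and the transcription factor RFXAP (0.98, adjusted p = 0.0735) did not pass. For MHC class I, 0 of 20 members rose or fell in limma, with 10 at an unadjusted p under 0.05 (all higher; median 0.87), including HLA-F at 1.48 (adjusted p = 0.0795), the peptide-trimming enzyme ERAP1 at 1.12 (adjusted p = 0.0611) and the proteasome activator PSME2 at 0.89 (adjusted p = 0.0882). Adjusted over the list alone, 15 class II and 9 class I members were higher and 0 lower. The shifts passed camera (adjusted p = 2.79e-07 for class II and 9.00e-05 for class I), each with adjusted p = 0.533 with an estimated correlation. Interferon-stimulated genes, which act against viruses, had a median of -0.47: 1 of 37 members fell, 0 rose and 36 did not pass. By line the interferon medians were -0.14, -0.67 and 0.21 against L428, L1236 and KMH2, the last in the other direction. IFI44L fell (-2.57 ± 0.119, adjusted p = 0.0216), beside its relative IFI44 (-2.49, adjusted p = 0.0533), the interferon regulator USP18 (-2.01, adjusted p = 0.0619) and the RNA sensor IFIH1 (-1.52, adjusted p = 0.0794), which did not pass. Adjusted over the list alone, 1 was higher and 6 lower. The interferon group did not pass (adjusted p = 0.0595), but passed with the replicate number as a block (adjusted p = 0.0214) and without KMH2 (adjusted p = 0.0130).

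**Figure D2:**
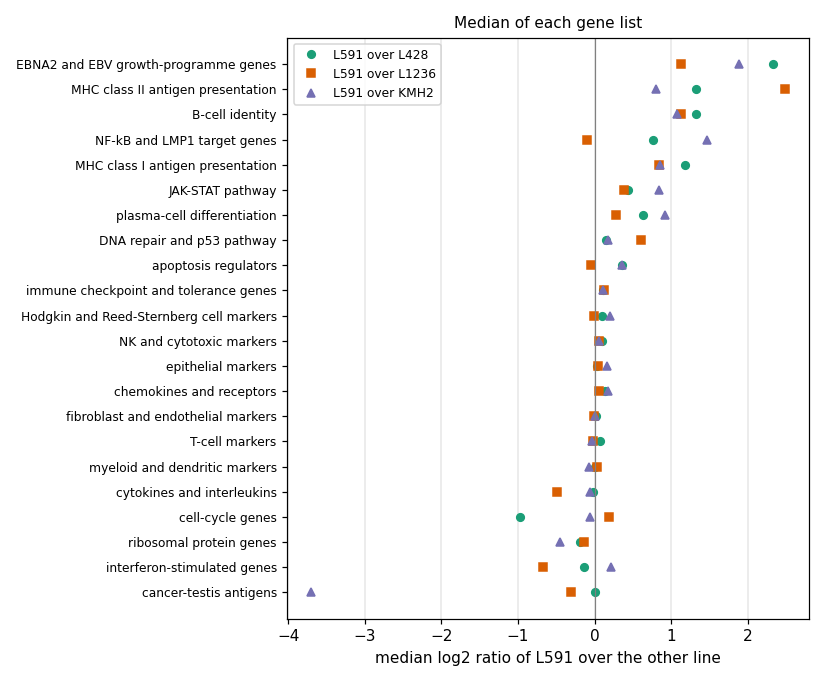
Median log2 ratio of L591 over each uninfected line (horizontal axis) for each of the 22 tested gene lists (vertical axis), with a symbol per line. Medians of the MHC class II list were 1.32, 2.48 and 0.80 against L428, L1236 and KMH2, and those of the cancer-testis list 0.0065, -0.32 and -3.70.

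JAK-STAT pathway genes, which carry cytokine signals, were higher as a group: 4 of 31 members rose, 0 fell and 27 did not pass (median 0.61). The feedback inhibitors SOCS3 (4.10 ± 0.154, adjusted p = 0.0179) and SOCS1 (1.59 ± 0.0933, adjusted p = 0.0278), the kinase PIM2 and the receptor chain IL2RB (3.19 ± 0.234, adjusted p = 0.0397) rose. A second SOCS3 probe passed at a smaller ratio (1.64, limma adjusted p = 0.0248). A further count gave 9 JAK-STAT members higher and 2 lower adjusted over the list alone. The shift passed camera (adjusted p = 0.00798; adjusted p = 0.533 with an estimated correlation), and its adjusted p was 0.111 without KMH2. Among Hodgkin and Reed-Sternberg cell markers, 2 of 30 rose, 0 fell and 28 did not pass (median 0.17, camera adjusted p = 0.454). The mucin MUC1 (2.41 ± 0.0852, adjusted p = 0.0166) and the tumour necrosis factor receptor TNFRSF1B (1.52 ± 0.0768, adjusted p = 0.0225) rose, and adjusted over the list alone 4 were higher and 2 lower. Of 34 cytokines, 2 rose, 0 fell and 32 did not pass (median -0.17, camera adjusted p = 0.564), namely the lymphocyte growth factor IL7 (2.64 ± 0.101, adjusted p = 0.0181) and EBI3, while IL12B was at 2.54 (adjusted p = 0.0939) and IL1A at 2.62 (adjusted p = 0.104). Among cytokines 4 were higher and 0 lower adjusted over the list alone. Of 35 chemokines and receptors, 2 rose, 0 fell and 33 did not pass (median 0.0035, camera adjusted p = 0.125, and 0.0456 without L1236). These were CXCL1 and CCL19, which guides lymphocytes to lymph nodes (2.90 ± 0.168, adjusted p = 0.0270), and CCL20 (4.27, adjusted p = 0.0532) and CCL28 (0.83, adjusted p = 0.0593) did not pass, the latter at least 1.84-, 1.83- and 1.68-fold higher than L428, L1236 and KMH2, where it was not well above background. Among chemokine genes 10 were higher and 1 lower adjusted over the list alone. Of 23 checkpoint genes, the inhibitory receptor BTLA rose (3.38 ± 0.107, adjusted p = 0.0155), 0 fell and 22 did not pass, TNFRSF14 (2.52, adjusted p = 0.0831) and HAVCR2 (2.26, adjusted p = 0.100) among them. The checkpoint median was 0.21, with 3 members higher and 0 lower adjusted over the list alone. Its camera adjusted p of 0.0729 became 0.0134 with the replicate number as a block, 0.0217 without L1236 and 0.0423 with the uneven spots kept.

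Cancer-testis antigens, normally restricted to germ cells, were lower as a group: 2 of 18 members fell (MAGEB2 and PRAME), 0 rose and 16 did not pass, among them MAGEB1 (-3.49, adjusted p = 0.0679). Their median was -1.39, but it differed by line, at 0.0065, -0.32 and -3.70 against L428, L1236 and KMH2. Adjusted over the list alone, 3 were lower and 0 higher, and the shift passed camera (adjusted p = 8.60e-05; adjusted p = 0.534 with an estimated correlation). Ribosomal protein genes were slightly lower: 1 of 46 fell, RPLP1 (-1.48 ± 0.111, adjusted p = 0.0413), 0 rose and 45 did not pass, RPL8 (-0.71, adjusted p = 0.0931) among them. A second RPLP1 probe did not pass (-1.40, limma adjusted p = 0.0645). The ribosomal median was -0.31, adjusted over the list alone 1 was lower and 0 higher, and camera gave an adjusted p of 0.00150 (adjusted p = 0.533 with an estimated correlation). Of 35 apoptosis regulators, 1 rose, the cell-death promoter BAD (1.19 ± 0.104, adjusted p = 0.0499), 0 fell and 34 did not pass, the survival factor MCL1 (1.01, adjusted p = 0.0819) and the inflammatory protease CASP1 (3.75, adjusted p = 0.0839) among them. The apoptosis median was 0.28 (camera adjusted p = 0.147, and 0.0284 without L1236), with 4 members higher and 0 lower adjusted over the list alone. Of 29 DNA repair and p53 genes, 1 rose, RRM2B, a subunit of ribonucleotide reductase (0.97 ± 0.0826, adjusted p = 0.0492), 0 fell and 28 did not pass. Their median was 0.36 (camera adjusted p = 0.200), and adjusted over the list alone 5 were higher and 2 lower. Cell-cycle genes did not differ detectably, with 0 of 35 past the threshold in limma, 0 adjusted over the list alone, 4 higher and 2 lower at an unadjusted p under 0.05, and a median of -0.28 (camera adjusted p = 0.338, and 0.0280 without L1236).

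Markers of other cell types gave small medians with single genes standing out. Of 22 T-cell markers, 2 rose, CD2 among them, 0 fell and 20 did not pass, including CD3E (0.03, adjusted p = 0.875) and GATA3 (-2.82, adjusted p = 0.122). The T-cell median was -0.02 (camera adjusted p = 0.697). Of 14 NK and cytotoxic markers, the granule protein NKG7 rose (2.47 ± 0.0802, adjusted p = 0.0155), 0 fell and 13 did not pass (median 0.06, camera adjusted p = 0.208). Of 17 myeloid markers, the inhibitory receptor LILRB1 rose (3.75 ± 0.101, adjusted p = 0.0155), 0 fell and 16 did not pass. LILRB1 was not well above background in the uninfected lines, so that L591 was at least 12.2-fold, 15.1-fold and 11.7-fold higher than L428, L1236 and KMH2 (adjusted p = 3.37e-10, 1.87e-10 and 2.03e-10). The SE and limma p of LILRB1 over the lines thus largely reflect how alike background signals were, not a spread of expression. The myeloid median was -0.06 and the mean 0.08 (camera direction down, adjusted p = 0.832). Of 11 epithelial markers, MUC1 and ELF3, an epithelial transcription factor (2.37 ± 0.0978, adjusted p = 0.0195), rose, 0 fell and 9 did not pass (median 0.04, camera adjusted p = 0.200, and 0.0439 with the replicate number as a block). None of 16 fibroblast and endothelial markers passed limma, with 1 lower at an unadjusted p under 0.05 (median -0.0067, camera adjusted p = 0.559). Adjusted over the list alone, 2 T-cell, 1 NK, 2 myeloid, 3 epithelial and 0 fibroblast markers were higher and 0 of any were lower.

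Of the 48 genes taken by the naming rule and past the threshold in this comparison, 34 kept the call under every planned setting that retained the 3 lines and measured them. The 14 others each lost it in at least 1 such setting, among them MMP7, PREX1, PRAME, IGF2BP1, EBI3, BATF, HLA-DOB, DERL3, SOCS1, CCL19, BAD, RRM2B and RPLP1. BAD lost the call in 12 of 15 such settings, RRM2B in 11, DERL3 in 7, and PREX1 and PRAME in 5, so that the calls of BAD and RRM2B held in few of them. All 48 lost it with the uneven spots kept, as in the fit made first, which is not among these settings. BANK1 and SYK were named outside the rule, and their calls were not followed over the settings.

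Further genes fixed in advance did not pass, and many of them differed in size by line. POU2AF1, a B-cell coactivator, was higher in L591 by 5.29, 1.14 and 5.36 against L428, L1236 and KMH2, the checkpoint ligand CD274 by 2.95, 0.51 and 3.55, and TRAF1, an adaptor of NF-kB signalling, by 0.88, 4.86 and 2.38. TNFAIP3, an NF-kB inhibitor, was higher by 1.13, 1.13 and 3.26, NFKBIA by 3.27, 0.14 and 0.84, and ID2, an inhibitor of B-cell transcription factors, by 2.24, 0.31 and 2.05. The chemokine CCL17 had ratios of -3.99, -4.64 and -0.97, the cytokine IL13 of -4.24, -4.79 and 0.11 (not well above background in KMH2), and FUT4, which makes the Hodgkin marker CD15, of -0.69, -1.82 and -0.34. The class II regulator CIITA had ratios of -0.02, 1.13 and 1.32. Mean ratios were 0.91 for IRF4, 0.80 for MYC, 0.46 for BCL2, 0.44 for SPI1 (not well above background in KMH2), 0.21 for TGFB1, -0.13 for PDCD1LG2, -0.17 for IL10 and -0.36 for FCER2. Adjusted p (limma, n = 3 lines) lay above the threshold for all of them. CR2 and BCL6 had no probe with a matched name, and LGALS1 was not tested.

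**Figure D3:**
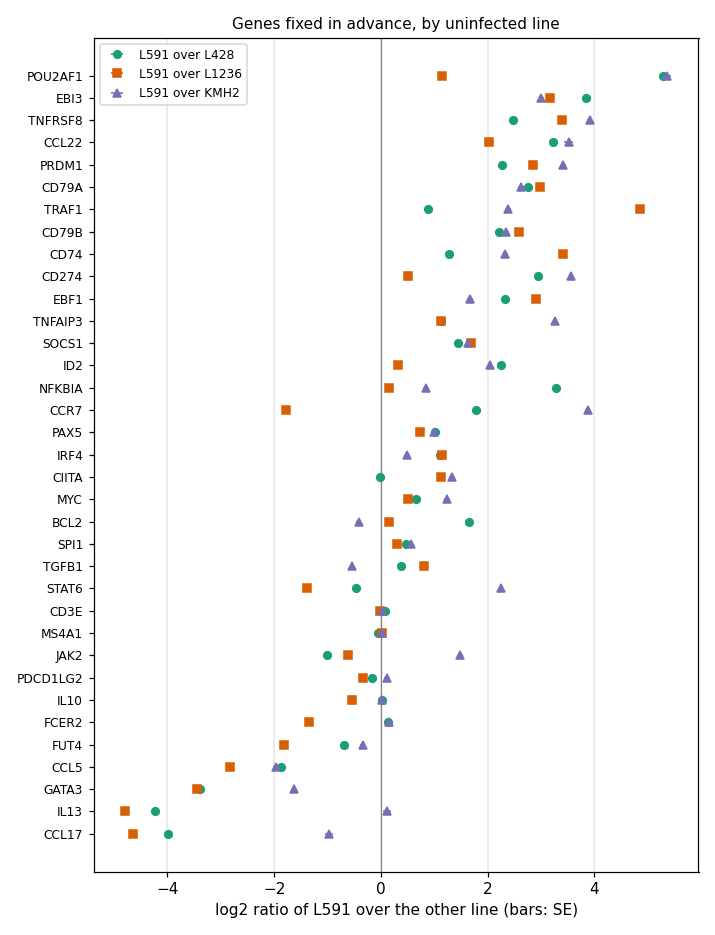
Log2 ratio of L591 over each uninfected line (horizontal axis) for genes fixed in advance (vertical axis), with a symbol per line and bars for the standard error. CD79A lay between 2.63 and 2.97 in the 3 comparisons, while CCR7 lay at 1.78, -1.79 and 3.88.

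Against L428 alone, L591 had higher levels of LARP6, a binder of collagen mRNA (6.35 ± 0.0427, adjusted p = 2.49e-13), the interferon-induced chemokine CXCL9 (6.32 ± 0.0578, adjusted p = 6.04e-13), the guidance receptor ROBO1 (6.12 ± 0.104, adjusted p = 1.12e-11), the heat-shock protein HSPA1A (5.94 ± 0.0711, adjusted p = 1.71e-12) and the lymphocyte surface protein CD48 (5.74 ± 0.0380, adjusted p = 2.49e-13). It had lower levels of DUSP6, a phosphatase of ERK kinases (-6.24 ± 0.100, adjusted p = 7.94e-12), the cancer-testis genes CT45A5 (-6.20 ± 0.0734) and CT45A1 (-5.62 ± 0.0509), the growth factor homologue FGF13 (-5.85 ± 0.0802) and the cytochrome CYP4Z1 (-5.65 ± 0.0795). FGF13 and CYP4Z1 were well above background in 6 of 10 L591 channels, CT45A1 in 7 and CT45A5 in 8, and ROBO1 in 1 of 2 L428 channels. Other probes gave smaller ratios against L428 for ROBO1 (2.30), CD48 (4.78) and HSPA1A (3.84 and 4.69), so these sizes depend on the probe. The cell-cycle list had a median of -0.97 against L428, compared with 0.18 against L1236 and -0.06 against KMH2. In limma over arrays, 22716 probes passed, 11400 higher and 11316 lower in L591, and 5240 of them differed by more than 1 on the log2 scale (2779 higher, 2461 lower). In this and the other single-line comparisons the p-values measured the spread between hybridisations (n = 2 arrays), not between cultures.

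Against L1236, the largest rises in L591 were in SMIM3 (7.54 ± 0.0970, adjusted p = 2.40e-12), the galectin LGALS3 (7.29 ± 0.0854, adjusted p = 1.73e-12), the G-protein subunit GNG11 (6.46 ± 0.0696, adjusted p = 1.23e-12), LARP6 (6.24 ± 0.0427, adjusted p = 4.61e-13) and the glutamate transporter SLC1A1 (6.08 ± 0.138, adjusted p = 7.22e-11). The largest falls were in PTGER4, a receptor for prostaglandin E (-7.08 ± 0.0562, adjusted p = 5.76e-13), the cancer-testis gene MAGEA9 (-5.95 ± 0.0685), the plasminogen activator PLAT (-5.78 ± 0.0511), TRIM15 (-5.58 ± 0.106) and the monocyte-attracting chemokine CCL2 (-5.57 ± 0.0435). TRIM15 was well above background in 4 of 10 L591 channels, and MAGEA9 and PLAT in 8. Second probes gave smaller ratios against L1236 for SLC1A1 (1.58), PTGER4 (-3.18) and TRIM15 (-3.10), so these sizes depend on the probe. MHC class II genes had their highest median of the 3 comparisons here, 2.48. In all, 24675 probes passed, 12373 higher and 12302 lower, and 5593 of them lay beyond 1 (2922 higher, 2671 lower). With scale normalization between arrays 15908 probes passed.

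Against KMH2, SMIM3 (7.59 ± 0.0970, adjusted p = 2.18e-12), LGALS3 (7.02 ± 0.0854, adjusted p = 1.73e-12), the oxysterol receptor GPR183 (6.42 ± 0.0967, adjusted p = 4.75e-12), the potassium channel KCNK1 (6.38 ± 0.0934, adjusted p = 4.12e-12) and the biliverdin reductase BLVRA (6.37 ± 0.0470, adjusted p = 3.29e-13) were higher in L591. MAGEA1 (-8.09 ± 0.0600, adjusted p = 3.29e-13) and MAGEA9 (-6.81 ± 0.0685, adjusted p = 8.15e-13), the joint lubricant PRG4 (-6.83 ± 0.0686, adjusted p = 8.15e-13), the actin-bundling protein PLS3 (-6.35 ± 0.104) and the signalling protein WNT5A (-6.01 ± 0.0905) were lower. PRG4 was well above background in only 1 of 10 L591 channels, MAGEA1 and WNT5A in 3, PLS3 in 5 and MAGEA9 in 8, so the sizes of these ratios rest on signals near background and are not exact. Cancer-testis antigens had a median of -3.70 against this line. In all, 24069 probes passed, 12229 higher and 11840 lower, and 6403 of them lay beyond 1 (3530 higher, 2873 lower).

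Of the tested probes, 1402 lay beyond 1 in the same direction in all 3 comparisons, 1087 higher and 315 lower in L591, and these covered 659 and 193 named genes. With L428, L1236 or KMH2 as the shared line in place of L591, 1130, 1394 and 2073 probes did so, and an overlap of this size was thus not special to L591. L428 and L1236 shared 1572 probes higher in L591, against 228 for independent lists, and 779 lower, against 185. L428 and KMH2 shared 1601 (276) and 749 (199), and L1236 and KMH2 shared 1556 (290) and 674 (216). Across probes, which are not independent replicates, the ratios correlated at 0.549, 0.502 and 0.457 for these pairs, with covariances of 0.402, 0.396 and 0.365. With L428, L1236 or KMH2 as the shared line the mean correlation was 0.43, 0.48 and 0.58, compared with 0.50 for L591, so any of the 4 lines gave correlations of about this size. Simulated unchanged lines gave a correlation of 0.0019 and a covariance of 6.5e-06, but from array noise alone. That simulation leaves out differences between lines, the independent lists leave out the shared L591, and the excess over either does not measure a shared effect. L591 RNA was on every array, so the 3 ratios share it and correlate for that reason even where no effect is shared. As any other shared line gave values of like size, the excess is no ground for an effect particular to L591.

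Some genes had far-apart ratios among the uninfected lines. MAGEA1 had L591 ratios of 0.08, -0.18 and -8.09 against L428, L1236 and KMH2 (adjusted p = 7.33e-12 for a difference between lines) and PRG4 of -0.03, -0.11 and -6.83 (adjusted p = 1.56e-11). PERP, a p53 target in cell adhesion, had ratios of -1.85, -1.12 and 5.32 (adjusted p = 3.90e-12), the growth factor relative HDGFL3 of -0.95, 0.36 and 6.21 (adjusted p = 2.31e-11) and the collagen-modifying enzyme P4HA2 of 0.01, -0.82 and 6.10 (adjusted p = 8.63e-12). HSPA1A had ratios of 5.94, 5.46 and -0.96 (adjusted p = 1.91e-11), and its other probes gave smaller ratios in the same directions. MAGEA1 was not well above background in L428, PRG4 was not in L428 or L1236, and in L591 they were so in only 3 and 1 of 10 channels. HDGFL3 was well above background in 1 of 2 KMH2 channels. An F-test in limma called 26689 of 35579 probes (75.0%), of which 10975 had a range beyond 1, but its error was the spread between hybridisations and not between cultures. Differences beyond 1 numbered 5450 between L1236 and L428, 6128 between KMH2 and L428 and 7153 between KMH2 and L1236, set against 5240 to 6403 between L591 and these lines. Each uninfected line was on its own slide, so line and slide cannot be told apart, though every ratio was measured within an array.

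The self-hybridisations gave the background of the method. With L591 in both dyes, 0 probes lay beyond 1 on either array and the log2 ratios had standard deviations of 0.138 and 0.128, against 0.854 to 0.950 on the arrays with an uninfected line, where 15.0% to 19.0% of probes lay beyond 1. The spread was 0.133 on average, 0.208 with Agilent's processed signals and 0.332 with median centring. Turned to the same direction, the arrays of each dye swap correlated across probes at 0.965, 0.967 and 0.973 for L428, L1236 and KMH2.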

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

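None of the tests in this part was chosen after its result was seen except the count of probes beyond 1 in opposite directions, which was set up after the single-line counts were known. The F-test between the uninfected lines called 26689 probes. Like the p-values per line below, it measured the spread between hybridisations and not between cultures, so a difference between single cultures would be called as well. At 497 probes, covering 301 named genes, L591 was higher than one line and lower than another, beyond 1 and past the threshold in both. The ratios of PERP spanned 7.17 on the log2 scale, from -1.85 against L428 to 5.32 against KMH2 (adjusted p = 3.90e-12, F-test in limma). CCR7, a receptor that guides lymphocytes, spanned 5.66, with L591 above L428 (1.78) and KMH2 (3.88) and below L1236 (-1.79; adjusted p = 1.09e-11). STAT6, the transcription factor downstream of IL-4 and IL-13, spanned 3.63, from -1.38 against L1236 to 2.26 against KMH2 (adjusted p = 3.09e-11). JAK2, a cytokine receptor kinase, spanned 2.50, from -1.01 against L428 to 1.49 against KMH2 (adjusted p = 2.21e-10). No group held enough arrays for a test of single outlying arrays.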

How the results depend on the processing

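The fit made first kept the uneven spots in the background model, and their removal was decided after the values were seen. The replicate block for the lists was chosen only after the results were seen. The count of 732 probes for L591 against the uninfected lines kept within a factor of 1.5 with no background correction (734, of which 714 shared), Agilent's processed signals (605, 535 shared), the series table (630, 564 shared), median centring (672, 652 shared), scale normalization (689, 594 shared), no filter (744, 700 shared) and the intensity trend (728), and without any 1 array (673 to 745). It was 405 with the strict filter, which tested 27490 probes, all 405 among the 732. It was 0 with the uneven spots kept (smallest adjusted p = 0.0725, 6370 probes at an unadjusted p under 0.05 in limma). Leaving out L428, L1236 or KMH2 gave 0, 0 and 0 probes in limma, with fewer lines and so fewer degrees of freedom (smallest adjusted p 0.231, 0.187 and 0.140, and 4857, 5549 and 5873 probes at an unadjusted p under 0.05). The replicate block, fitted on 6 arrays with the replicate number as a fixed block and the line as a random block (consensus correlation 0.955), gave 3875 probes, 64.2% of them higher. This fit counts both arrays of a swap as observations with 1 common correlation, though they may hold the same RNA extract. Its larger count and its list calls carry that limit, and whether this alone made the count larger was not tested. For L591 against L1236, scale normalization gave 15908 probes, and the cause was not tested. The other counts per line, between lines and in all 3 lines stayed within a factor of 1.5 under each setting.

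Of the gene lists 8 passed, 0 in camera with an estimated correlation (1 at an unadjusted p under 0.05), and 7 to 13 with 1 line left out, 13 of them without L1236. The estimates were -0.019 for B-cell identity and 0.0092 for ribosomal genes, not above the preset 0.01, and both lists lost the call. That setting, with its degrees of freedom from 3 lines, cannot show that correlation removed the shifts. With the replicate block 11 passed, the interferon, checkpoint and epithelial lists being added, and no other list call changed. No setting that reversed a list's direction left it past the threshold (6 of 176 pairs of list and setting). Some medians moved in size. The B-cell identity median of 1.08 ran from 0.86 (scale normalization) to 1.84 (strict filter). The Hodgkin marker median of 0.17 ran from 0.10 (scale normalization) to 0.90 (strict filter). The self-hybridisation spread of 0.133 became 0.208 with Agilent's signals and 0.332 with median centring, the latter without the loess that removes dye trends. The median of all probes shifted by less than 0.1 under each setting (-0.0478 to 0.0041). Over 2871 pairs of a gene's value and a setting, 2537 kept direction and side of the threshold, 252 lost and 67 gained the call, and 15 reversed, none of a called gene. JAK2 (reported at -0.05) was 0.0266 with Agilent's signals and with the series table, and MS4A1 (-0.01) was 0.0035 with the uneven spots kept and ran from -0.0673 to 0.047 without 1 array, being 0.016 without L428. With 1 line left out, JAK2 ran from -0.82 (without KMH2) to 0.44 (without L428), BCL2 from -0.13 (without L428) to 0.90, FCER2 from -0.61 to 0.14, IL10 from -0.27 to 0.016 and TGFB1 from 0.59 down to -0.086 (all without L1236), CCR7 from -0.0043 to 2.83 and STAT6 from -0.92 to 0.90 (both lowest without KMH2). The causes were not tested. All 48 named calls were lost without any 1 line and with the uneven spots kept. Signal over background was lowest in Cy3, at 73.3% of spots on one self-hybridisation, which limits small differences of dim probes.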

Other observations

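The tests on the split of the lines, on EBV and on T-cell RNA were chosen only after the results were seen, and those on ribosomal genes before. Set each in turn against the other lines, the uninfected lines had gene groups of their own, given as list medians without a test. KMH2 stood apart in cancer-testis antigens (2.79), with L428 at -1.08 and L1236 at -0.13. L428 had the highest cell-cycle median (1.04), against -0.69 for L1236 and 0.0094 for KMH2. L1236 had the lowest MHC class II median (-1.49) and the highest for interferon-stimulated genes (0.69), with KMH2 lowest in the latter (-0.77). NF-kB targets were at 0.81 for L1236, near the 0.90 of L591, and at -0.76 and -0.80 for L428 and KMH2.

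The difference of L591 from the uninfected lines may be tied to its EBV infection or to any other property of that line. Set against the remaining lines, 2 of the 4 lines gave as many probes as L591 or more, L591 itself included: L591 gave 732 and KMH2 2266, with 602 for L1236 and 39 for L428. These counts moved with the processing, for L591 between 0 in limma (uneven spots kept, 6370 probes at an unadjusted p under 0.05) and 744, for L1236 between 79 (strict filter) and 1274 (uneven spots kept), and for L428 between 0 in 4 settings (4865 to 6214 at an unadjusted p under 0.05) and 367 (scale normalization). With 4 splits no share under 0.05 can be reached. KMH2 gave the most probes in every setting (1356 to 3148), so a large count was not particular to L591, and its cause was not tested. The EBNA2 list median was 1.85 for L591 and at most 0.147 for another line, the direction infection would give, but with 1 infected line EBV and other features of L591 cannot be told apart.

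CD2 was higher in L591, and RNA of T cells in the culture was a candidate source. T cells would bring the receptor complex genes CD3D, CD3E, CD3G and CD247 too. The largest sum of a value and 2 of its standard errors was 0.522, for CD3D (-1.27 ± 0.897), which was near background in L591. This lay far below 3.33, a bound taken as a fraction of the CD2 ratio after the results were seen. The median of the complex genes was -0.36. Only CD3E of the 4 was well above background in every L591 channel, at a ratio of 0.03. T-cell RNA is thus argued against as the whole source, and expression by L591 itself remains open and untested.

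Ribosomal protein genes were lower in L591 (median -0.31, 34 of 46 below 0), and a trend of bright probes or the loess could have made this. Of 10000 lists matched on mean intensity, 0.01% had a median as low and the random lists had a median of 0.27. With median centring in place of loess the median was -0.33 (bootstrap SE 0.0828). Both explanations are argued against as the whole cause, and medians ran from -0.43 to -0.26 over all processing settings. Set against the other lines, KMH2 gave 0.32, L428 0.11 and L1236 -0.11. Only KMH2 thus differed by as much as L591, in the other direction. Both values contain the ratio between L591 and KMH2, so they are not separate deviations. By line, the L591 medians were -0.196, -0.145 and -0.449 against L428, L1236 and KMH2. No biological cause was tested.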
